A study of Mus musculus with 6 samples.

How the data were processed

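Splenic NK cells of both genotypes were cross-linked for 10 minutes in 1% formaldehyde, and inserts of 100 to 400 bp were kept for single-end sequencing of 100 bases, per the labels. The submitters' processing notes name Bowtie2 2.1.0 and MACS 1.4, and the builds mm10, GRCm38 and GRCh37 with no role for each. Which build was used for which step, the peak calling settings and the control track were not given in the sources used here. Positions and Ensembl identifiers in the lists are those of mouse, and they were read as GRCm38/mm10. Peaks were called per library, 1 list for each of the 4 antibody libraries, and input libraries were not analysed here.

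For each peak the deposited lists give the count of tags, not scaled to depth. The score is 10 times the negative log10 of the peak caller's p-value, per the file headers, with a ceiling of about 3100. The deposited fold enrichment is the ratio of the peak over a background of the peak caller. The deposited FDR is in percent. Each list held 1 row per peak and gene feature, so rows were reduced to distinct peaks. Starts counted from 0 (3 peaks start at 0) and were converted to count from 1.

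Gene positions came from a RefSeq table of assembly GRCm38.p6, which holds 21883 protein-coding genes on the placed chromosomes. It gives no strand, so strand and a second 5' end were taken from the Ensembl features in the lists, by Entrez identifier for 13412 genes and by at least 50% reciprocal overlap for 144. Of the remaining genes, 595 had an H3K4me3 peak within 2.5 kb of an end and were left out, since their TSS was unknown, and 21288 genes were kept. This rule used the H3K4me3 peaks themselves, so shares of marked genes are approximate. Without exon positions, peaks were placed at promoters, in genes or between genes, not in exons or introns as planned. The planned search for Tcf/Lef motifs was not run, because no genome sequence was used here.

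Peaks were compared by overlap of at least 1 bp, with 95% Wilson intervals and 1000 circular shifts within chromosomes. A gene was marked if an H3K4me3 peak came within 1 kb of its TSS. Tags of such peaks were summed, and the log2 ratio of KO over WT was centred on the median of genes marked in both. A sum over peaks called separately moves with their width, so ratios per kb of peak were computed as well. Counting intervals of a ratio assume Poisson counts. PCR copies were not identified, so these intervals and the Wilson intervals cover counting error only. The 14 gene lists held 248 distinct genes, of which 244 were measured. A list's median was placed among medians of 10000 random lists of equal size matched in 20 bins of mean log2 tags. The percentile describes these libraries and is no p-value. Bootstrap intervals used 2000 draws of the genes. Counts of genes within 50 kb of a Tcf1 peak were set against 10000 random lists matched in 20 bins of gene length and on H3K4me3 in WT.

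Lists, comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Tcf7, all granzymes, up to 4 members per other list with the strongest WT-only Tcf1 peak within 50 kb, and the 10 WT-only Tcf1 peaks of highest score. For H3K4me3 it took the 10 genes with most tags marked in WT alone and in KO alone, and the 10 highest and 10 lowest ratios among genes with at least 100 tags in both. It also took list members marked in 1 genotype, or with a ratio beyond 1 in size and at least 100 tags in 1 library. Alternatives were scores of at least 100, FDR of at most 1%, overlap of 50% of the shorter peak, summits within 200 bp, lists of equal length, autosomes and X alone, promoter windows of 0 and 2.5 kb, distances of 10 and 100 kb, and tags per kb. Merged regions of both libraries were added after the data were seen.

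The methods were tested on simulated data. For the overlap of Tcf1 lists, 173 of 866 simulated peaks were placed on KO peaks and all 173 were found, with 175 found in total. The 173 had the exact bounds of KO peaks, so finding them was certain and checks the code alone. For the tag ratios, 200 of 10010 genes were changed by 1 on the log2 scale, and 196 were recovered in the right direction beyond 0.5. Simulated counts were drawn per gene with no change of peak boundaries, so errors from separately called peaks are not covered. Of 100 unchanged lists of 15 genes, 7 fell outside the middle 95% of random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.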

Results

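Natural killer (NK) cells are lymphocytes that kill infected or transformed cells with perforin and granzymes. Here they came from the spleens of mice with an intact Tcf7 gene (WT) and of mice lacking Tcf7 (KO). The labels give the strain as B6 for WT and B6.129 for KO, so strain background and genotype are not separate here. The cells were grown for 5 days with 500 ng/mL IL-2, a cytokine that activates and expands them. Tcf7 encodes Tcf1, a DNA-binding protein of the Tcf/Lef family that acts in Wnt signalling. Chromatin was precipitated with an antibody against Tcf1 or against H3K4me3, a histone mark of active promoters. The labels give 6 libraries in 6 groups, which are input, Tcf1 and H3K4me3 for each genotype. Each group held 1 library, so no difference below has a replicate check and no p-value is given across genes. A peak list was analysed for each of the 4 antibody libraries.

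The WT Tcf1 list held 866 peaks with 74849 tags (reads counted in the peaks), and the KO Tcf1 list held 5139 peaks with 129810 tags. The WT H3K4me3 list held 13771 peaks with 6635272 tags over 30354 kb, a mean of 218.6 tags per kb. The KO H3K4me3 list held 11074 peaks with 7507763 tags over 25124 kb, a mean of 298.8 tags per kb. These sums cover called peaks and are not sequencing depths, which are unknown here. Intervals given below cover counting error only. The score, fold enrichment and false discovery rate (FDR) of each peak are the authors' values, used to describe, rank or filter peaks within a list.

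The targeted gene was examined first. A Tcf1 peak covered the transcription start site (TSS) of Tcf7 in WT, on chromosome 11 from 52282921 to 52283707 (GRCm38/mm10), with 123 tags and a score of 479. No Tcf1 peak was called in the gene in KO. The promoter of Tcf7 (gene at 52246527 to 52283383, minus strand) carried H3K4me3 in both genotypes, with 525 tags in WT and 535 in KO. Its log2 ratio of KO over WT, centred on the median gene, was -0.24 (95% counting interval -0.41 to -0.07), and 0.06 when tags were taken per kb of peak. A mark at the promoter does not measure the Tcf1 protein.

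The first comparison asked where the Tcf1 antibody enriched DNA in WT cells and not in cells without its target. Of the 10 peaks of highest score called in WT alone, 4 lay at genes of the Tcf/Lef and Wnt list. The highest score belonged to a peak over the TSS of Axin2, which encodes a feedback inhibitor of Wnt signalling (chromosome 11, 108920078 to 108921595). It held 251 tags with a score of 1378, but an FDR of 33.3%. WT peaks of still higher score, called in both genotypes, had FDRs of 100% and 50%. At the top of the list the FDR thus did not rank peaks by strength. The peak at the TSS of Tcf7 itself ranked 4. Peaks in Nkd1, another Wnt inhibitor (chromosome 8, 88570515 to 88571105), with 89 tags, and 4.21 kb upstream of Lef1, which encodes a close relative of Tcf1 (chromosome 3, 131105576 to 131106506), with 113 tags, ranked 8 and 9.

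The other peaks among the 10 of highest score lay at less related genes. Peaks were centred 0.19 kb from the TSS of Cyb5r4 (154 tags, FDR 20%), 0.133 kb from that of 1190007I07Rik (132 tags), 0.217 kb from that of Zfp703 (109 tags) and 0.513 kb from that of Fgf18 (85 tags). The nearest protein-coding TSS to the peak ranked 3 was that of Hsp90b1, 20.06 kb away (135 tags). The peak ranked 10 lay inside Dhx34, 20.62 kb from its TSS (85 tags). Of these 10 peaks, those at Nkd1, Lef1 and Dhx34 did not overlap an H3K4me3 peak in WT.

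Of the 866 WT peaks, 115 (13.3%, 95% Wilson interval 11.2 to 15.7%) overlapped a KO peak by at least 1 bp, and 751 did not. In 1000 random circular shifts of the WT peaks along their chromosomes, a mean of 1.62 and at most 8 overlapped. The 115 peaks called in both held a median of 107 tags in WT, against 21 for those called in WT alone. The tallest, over the ribosomal RNA locus Rn18s-rs5 on chromosome 17 (39842835 to 39848979), held 11097 tags in WT and 11235 in KO, with fold enrichments of 2.01 and 2.75. With scores of at least 100 required in both lists, 53 of 98 WT peaks (54.1%) overlapped a KO peak. No peak of either Tcf1 list had an FDR of 1% or less, and the lowest FDR was 3.45% in WT and 3.12% in KO. The median FDR was 26.6% in WT and 96.9% in KO.

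Fixed gene lists were then compared with the WT-only Tcf1 peaks. Of 20 Tcf/Lef family genes and Wnt targets, 7 had such a peak in the gene or within 50 kb. They were Axin2, Tcf7, Nkd1, Lef1, Lgr5, Tnfrsf19 and Rnf43, the last 3 of which were named after their values were seen. The mean over 10000 random lists matched on gene length and H3K4me3 was 0.905, and 0 of them reached 7. With peaks of score at least 100, 6 of the 20 genes remained near a peak, against a random mean of 0.0756. Peaks called in KO alone lay near 3 of the 20, below the random mean of 4.56.

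**Figure D1:**
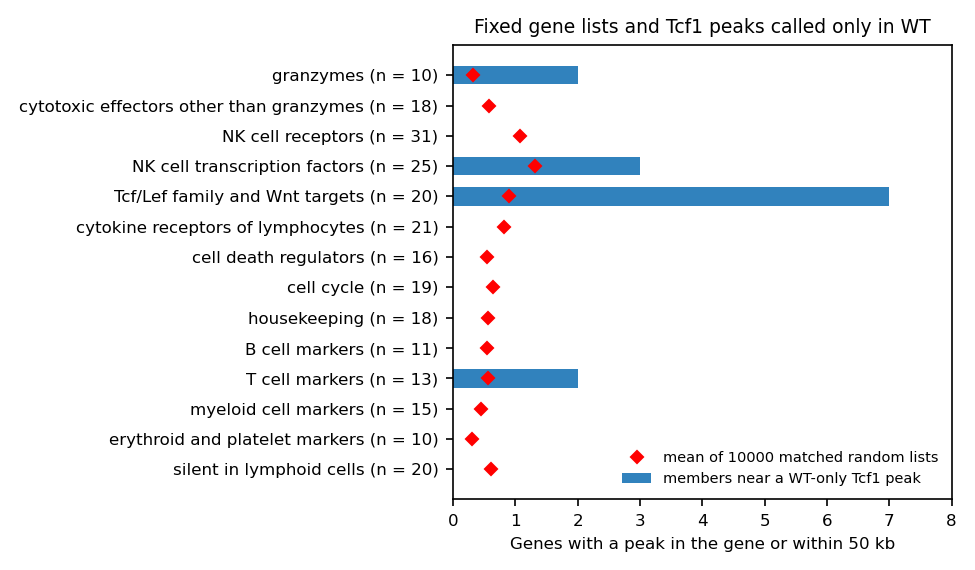
Number of genes in each fixed list with a Tcf1 peak called only in WT in the gene or within 50 kb (bars; n is the number of measured genes), with the mean of 10000 matched random lists (diamonds). The Tcf/Lef and Wnt list holds 7 such genes against a random mean of 0.905.

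Granzymes, the proteases named in the title of the series, were near a single WT-only Tcf1 peak. It lay on chromosome 14 from 56287808 to 56288339, between genes and 25.8 kb upstream of the TSS of Gzmb. It was weak by tags (36) and score (55.1), had an FDR of 27.0%, and overlapped no H3K4me3 peak in either genotype. Because Gzmc also lay within 50 kb, the count was 2 of 10 granzymes, a number reached by 402 of 10000 random lists (4.02%). The count was 0 at a distance of 10 kb and 0 with scores of at least 100. In the KO list, a pair of peaks lay within 50 kb of 5 granzymes (Gzmc, Gzmf, Gzmg, Gzmk and Gzmn), a number reached by 47 random lists. They held 19 and 15 tags, each at an FDR of 100%. The random lists drew genes singly, whereas many granzymes lie together on chromosome 14 and can share a peak. Both comparisons with random lists thus likely overstate how unusual the granzyme counts were.

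**Figure D2:**
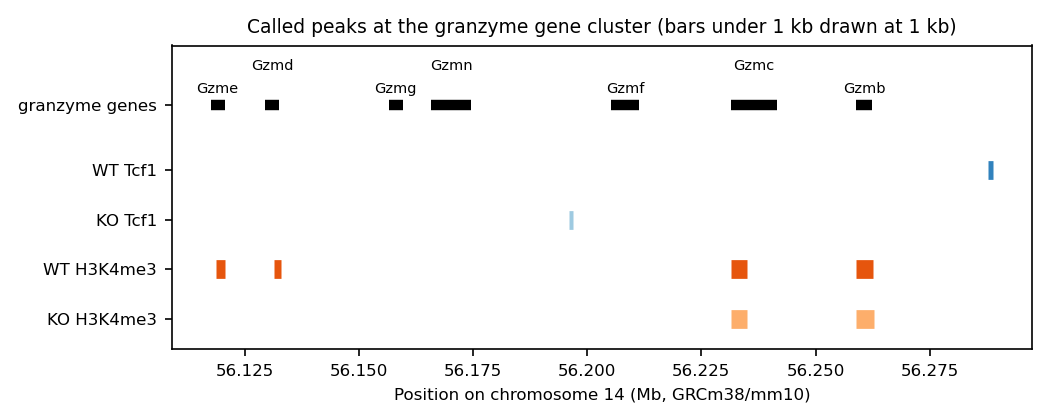
Peaks called in the 4 libraries along the granzyme gene cluster on chromosome 14 (position in Mb), with the granzyme genes above. The WT Tcf1 peak at 56287808 lies outside the genes, and H3K4me3 peaks at Gzme and Gzmd appear in WT alone.

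Among 25 measured NK cell transcription factor genes, 3 had a WT-only Tcf1 peak within 50 kb, and 14.5% of random lists had as many. The peaks lay inside Zeb2 (31 tags), inside Prdm1 (37 tags) and 17.7 kb beyond Tbx21 (25 tags), which encode regulators of NK cell maturation. Among 13 measured T cell markers the count was 2, at Cd5 (27 tags) and Foxp3 (33 tags), and 10.4% of random lists had as many. None of these 5 peaks reached a score of 100. No member of the lists of other cytotoxic effectors, NK cell receptors, cytokine receptors, cell death regulators, cell cycle genes, housekeeping genes, B cell, myeloid or erythroid markers or silent genes had one within 50 kb.

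Tcf1 peaks were next placed relative to promoters and to H3K4me3. Peaks called in WT alone lay at promoters more often than shifted peaks, most of all the strong ones. The mean of the shifts is too low here, because only promoters of genes of known strand counted. Strand came from features listed with these same peaks, and 8327 of 21883 genes had none. The size of the excess thus cannot be told, nor whether KO-only peaks had one. Of 751, 35 (4.66%, interval 3.37 to 6.41%) had their summit within 1 kb of a protein-coding TSS, against a mean of 8.08 in the random shifts. Of the 43 with a score of at least 100, 9 did (20.9%, interval 11.4 to 35.2%), against a mean of 0.455. Most WT-only peaks lay elsewhere, 311 in genes outside promoters, 390 between genes and 15 on unplaced contigs. Among KO-only peaks 109 of 5024 (2.17%) were at promoters, against 55.5 in the shifts, and of the 187 with a score of at least 100 there were 5, a number reached by 58 of 1000 shifts.

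Overlap with WT H3K4me3 peaks was seen for 37 of 751 WT-only Tcf1 peaks (4.93%, interval 3.60 to 6.72%), against 10.3 in the shifts. It was seen for 10 of 43 strong ones (23.3%, interval 13.2 to 37.7%). Tcf1 peaks called in both genotypes overlapped WT H3K4me3 peaks in 62 of 115 cases (53.9%), although 1 of the 115 lay at a promoter. Only 15 of the 115 (13.0%) overlapped a KO H3K4me3 peak. KO-only Tcf1 peaks overlapped a WT H3K4me3 peak in 197 cases (3.92%) and a KO H3K4me3 peak in 91 (1.81%). Of the 187 KO-only peaks with a score of at least 100, 28 (14.97%, interval 10.6 to 20.8%) overlapped a WT H3K4me3 peak, against a mean of 2.99 in the shifts.

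**Figure D3:**
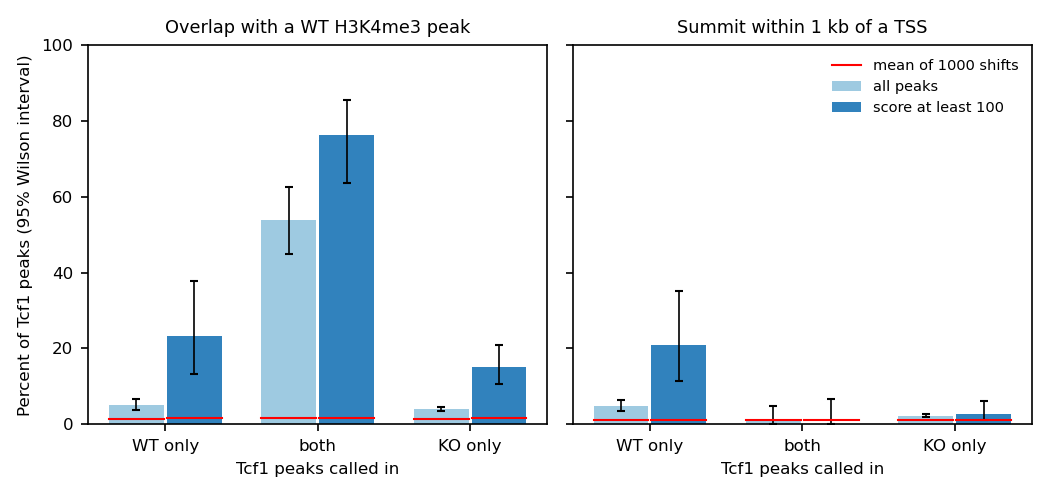
Percent of Tcf1 peaks called in WT only, in both genotypes or in KO only that overlap a WT H3K4me3 peak (left) or have their summit within 1 kb of a TSS (right). Bars carry 95% Wilson intervals and red lines mark the mean of 1000 random shifts. On the right this mean is too low, because genes of unknown strand could not count. Among WT-only peaks with a score of at least 100, 20.9% were at a TSS.

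The genotypes were then compared for H3K4me3 across promoters. Most marked promoters were marked in both. Of 21288 protein-coding genes, 10010 had an H3K4me3 peak within 1 kb of the TSS in both libraries, 1249 in WT alone, 35 in KO alone and 9994 in neither. The WT-only promoters were weakly marked, with a median of 75 tags in WT, against 559 for promoters marked in both. With lists of equal length the split was 480 in WT alone and 137 in KO alone. Of all WT H3K4me3 peaks, 10669 (77.5%, interval 76.8 to 78.2%) overlapped a KO peak, and 10678 of 11074 KO peaks (96.4%, interval 96.1 to 96.8%) overlapped a WT peak.

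The 10 genes marked in WT alone with the most tags were listed. Among them were Fcgr3, which encodes an activating Fc receptor of NK cells (493 tags), the MHC class II gene H2-Ab1 (520) and Ltb4r1, which encodes a leukotriene receptor (453). Others were Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors (670), the clock gene Dbp (544), and Hjurp and Trpm8, which shared 1 peak of 1747 tags. Add3 (842), Bahcc1 (723) and Apof (404) were also in this group, but a KO peak adjoined the window. When overlapping peaks of both libraries were merged into regions, an alternative chosen after the data were seen, these 3 were marked in both genotypes. The ratios there were -0.09 for Add3 and 0.02 for Apof, but -2.04 for Bahcc1, with 723 tags in WT and 211 in KO.

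Promoters marked in KO alone carried fewer tags. They included Klrg1, an inhibitory receptor gene of mature NK cells (158 tags), Klra9, of the Ly49 receptor family (110), Crtam, which encodes an adhesion receptor of activated lymphocytes (90), and the histone gene H2ac1 (67). The Y-linked genes Ddx3y (116), Eif2s3y (96) and Uty (80) also belonged to this group. Tjp3 (696), Rnf220 (519) and Cdhr4 (340) stood in it by peak boundaries, and were marked in both genotypes on merged regions. Rnf220 was still higher in KO there, with 64 tags in WT and 519 in KO (2.75), while Tjp3 had a ratio of 0.27 and Cdhr4 of 0.21.

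At promoters marked in both, KO held a median of 1.20 times the tags of WT, a log2 ratio of 0.27, and ratios are given relative to it. The centred ratios had an SD of 0.30 across genes. Among genes with at least 100 tags in 1 or both libraries, 12 lay above 1 and 138 below -1 on the log2 scale. On merged regions 6 and 121 did, and per kb of peak 1 and 72. The lowest ratios that held on merged regions were those of Kbtbd11 (-2.67, 631 tags in WT and 119 in KO), Ak4, an adenylate kinase gene (-2.54, 988 and 205), Vegfa, which encodes an angiogenic growth factor (-2.04, 2511 and 733), and Rgs11 (-1.94, 498 and 156). These 4 came to -1.88, -2.13, -1.22 and -1.11 per kb of peak, an alternative fixed beforehand, with WT peaks wider than KO peaks at each. Ratios of Slc35a2 (-2.94), Tyrobp (-2.34), Fuz (-2.31), H2-Ke6 (-2.08), Srebf1 (-1.94) and Cdk2ap2 (-1.90) shrank to -0.33 or nearer 0 on merged regions. Per kb of peak these 6 came to -0.83, -0.19, -0.98, -0.94, -0.71 and -0.80. For these 6 the WT peaks were wider than those at the KO promoter, as at Tyrobp with 12523 bp in WT and 2729 bp in KO.

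The highest ratios that held on merged regions belonged to Gpx8 (1.15), the chemokine gene Xcl1 (1.07, 252 tags in WT and 636 in KO), Tnfsf8 (0.99) and Iqgap3 (0.97). Taken per kb, these 4 came to 0.37, 0.79, 0.27 and 0.76, and at Gpx8 and Tnfsf8 the KO peaks were wider (3042 against 1838 bp and 3323 against 2100 bp). Those of Pik3c3 (1.47), Sp110 (1.38) and the histone genes H2bc23 and H2ac23 (1.24 each, sharing their tags) came to 0.73, 0.76 and 0.59, but per kb of peak to 0.17, -0.19 and -0.10. Those of Hspb9 (2.26) and Mrpl54 (1.395) turned to -0.07 and -0.14, and were 1.38 and 0.39 per kb.

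Cell cycle genes stood out among the fixed lists. Of 19 members, all marked in both libraries, 18 had a ratio above 0, and 17 of these had a counting interval above 0. Their median was 0.56 (95% bootstrap interval over genes 0.35 to 0.66), at percentile 100 of 10000 random lists matched on tag level. Examples chosen after their values were seen were Mcm2, of the replicative helicase (0.77), Rrm2, of ribonucleotide reductase (0.72), and Cdk1, the mitotic kinase (0.68). The exception was E2f1 at -0.10 (interval -0.24 to 0.03). Per kb of peak the list's median was 0.47, again at percentile 100.

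**Figure D4:**
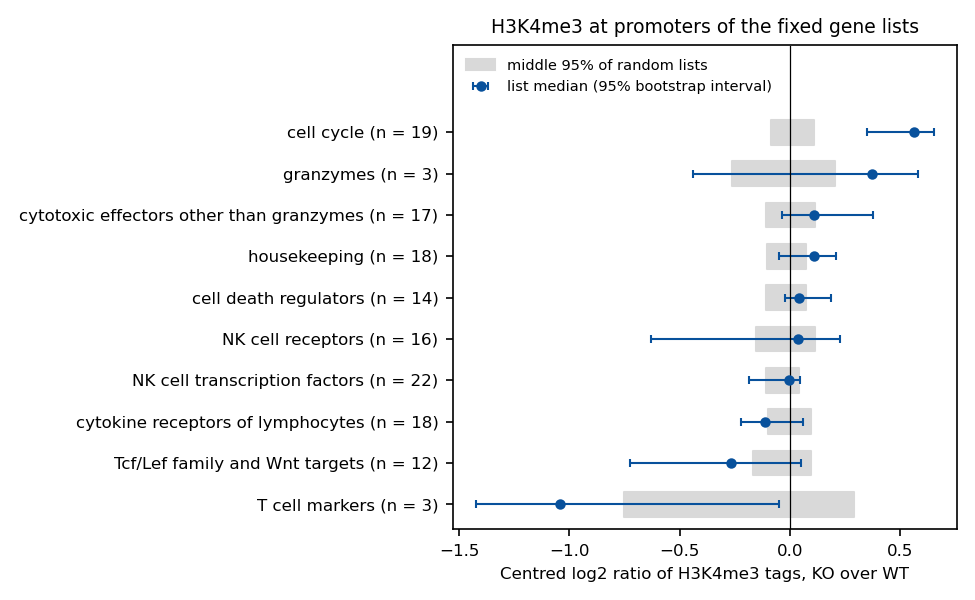
Median centred log2 ratio of H3K4me3 tags, KO over WT, for the fixed lists with at least 3 genes marked in both libraries (points, with 95% bootstrap intervals over genes), and the middle 95% of medians of matched random lists (grey). The cell cycle list, at 0.56, lies outside the grey range with its whole interval.

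Granzymes differed among themselves. Gzma carried 1461 tags in WT and 2273 in KO (0.37, counting interval 0.28 to 0.47), and Gzmb carried 1022 and 1842 (0.58, interval 0.47 to 0.69). Gzmc was lower in KO, with 353 and 313 tags (-0.44, interval -0.66 to -0.22). The 3 came to 0.57, 0.49 and -0.47 per kb of peak. Gzmd (64 tags) and Gzme (81 tags) were marked in WT alone, and Gzmf, Gzmg, Gzmk, Gzmm and Gzmn in neither library. A count of 2 marked in WT alone lay at percentile 93.4 of random lists (mean 0.589). Over all genes, promoters marked in WT alone had a median of 75 tags. The median of the 3 marked in both was 0.37, at percentile 99.9 of random lists, with a bootstrap interval of -0.44 to 0.58 that spans 0.

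Other cytotoxic effectors were marked in 17 of 18 cases in each library. Their median was 0.11 (percentile 97.2), with 11 members above 0 and 6 below. By tags the chemokine genes led the list, with Xcl1 at 1.07 and, chosen after their values were seen, Ccl3 at 0.87, Ccl4 at 0.78 and Ccl5 at 0.61. Per kb of peak these 4 came to 0.79, 0.88, 0.67 and 0.61. Tnfsf10, at 0.38 by tags, came to 0.84 per kb and 0.80 on merged regions, so the order depended on the measure. Annotated ends of Ccl3 and Ccl4 lie within 1 kb of each other, so the 2 genes can share a peak. The perforin gene Prf1 (-0.28, interval -0.39 to -0.18) and Ifng (-0.14, interval -0.37 to 0.09) did not follow them. Housekeeping genes had the same median of 0.11 at percentile 99.7, so a percentile this high did not set the effectors apart from them.

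Genes of the NK cell receptor list went both ways. Of 31, 16 were marked in both libraries with a median of 0.04 (percentile 78.4). The median changed sign to -0.04 with a promoter window of 2.5 kb (percentile 33.3) and on merged regions (percentile 35.5), and was 0.11 per kb of peak (percentile 96.2). Fcgr3 (493 tags), Klrc1, which encodes the inhibitory receptor NKG2A (211), Klra4 (99) and Klra3 (23) were marked in WT alone, and Klrg1 (158) and Klra9 (110) in KO alone. Ly49 (Klra) genes differ between mouse strains, and the labels name different strains for the genotypes. Klrd1, which encodes CD94, the partner of NKG2A, had 452 tags in WT and 236 in KO (-1.20), but 0.23 per kb of peak. NK cell transcription factor genes were marked in 22 of 25 cases in each library, with a median of -0.0045 (percentile 77.4).

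The Tcf/Lef and Wnt list had a median of -0.27 (bootstrap interval -0.72 to 0.05) over 12 genes, at percentile 0.15. Per kb of peak it was -0.02 at percentile 54.6, so the position of the list depended on the measure. Axin2 was lower in KO on both measures, with 453 and 247 tags (-1.14, interval -1.37 to -0.92) and -0.78 per kb. Apcdd1, a Wnt target, was marked in WT alone (100 tags). Cytokine receptor genes had a median of -0.11 at percentile 1.59, which turned to 0.13 at percentile 97.2 per kb of peak. Il2ra, the IL-2 receptor alpha chain gene, had 116 tags in WT and 54 in KO (-1.37), but -0.03 per kb, and Ifngr2 was marked in WT alone (62 tags). Cell death regulators had a median of 0.04 (percentile 90.2), and of these Fas was marked in WT alone (79 tags).

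**Figure D5:**
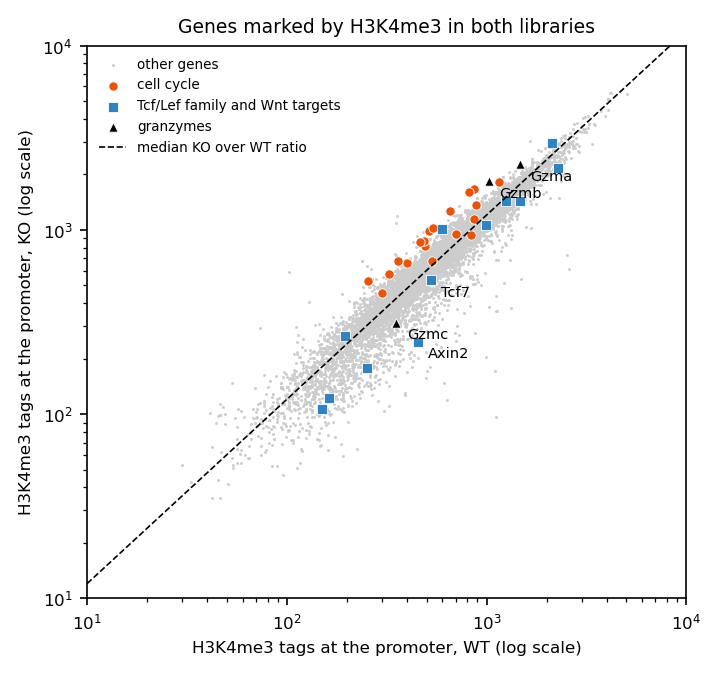
H3K4me3 tags at promoters of genes marked in both libraries, WT against KO, both axes on a log scale. Each point is a gene, coloured for 3 fixed lists, and the dashed line marks the median KO over WT ratio of 1.20. Gzma and Gzmb lie above the line, Gzmc and Axin2 below it.

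Markers of B, myeloid and erythroid cells or platelets were rarely marked. All 11 measured B cell markers and all 20 genes silent in lymphoid cells were unmarked in both libraries. Genes of unknown strand were left out if a peak lay near an end, and otherwise counted as unmarked. Marked members can thus be missing, as 11 of 12 B cell, 15 of 16 myeloid and 13 of 14 T cell markers were measured. Of 15 myeloid markers, Cd14 (95 tags) and Cebpa (113 tags) were marked in WT alone. Of 10 erythroid and platelet markers, Epor (56 tags) was marked in WT alone and Klf1 in both. T cell markers were not rare, with 6 of 13 marked in WT, near the random mean of 6.87, and 3 in KO, against 6.12. Most marked T cell markers had fewer tags or no peak in KO. Cd3e (64 tags), Cd3d (35) and Ctla4 (153) were marked in WT alone, Icos had a ratio of -1.42 and Cd28 of -1.04, and Bcl11b had -0.05. The median over these last 3 genes was -1.04, at percentile 0.28, and -0.62 per kb of peak, at percentile 1.66, where Icos had -1.11 and Cd28 -0.62.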

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

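The tests of Y-linked genes and of other peaks on Y were chosen after the results were seen, and the test of library sensitivity was fixed before its result was seen. Data outside the main comparisons held 3 signals. The TSS of 4 Y-linked genes carried H3K4me3 peaks in KO and not in WT. An H3K4me3 peak of 88 tags was called inside Tcf7 in KO alone. On unplaced contigs, 15 Tcf1 peaks were called in WT alone.

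The Y-linked genes were Kdm5d (48 tags), Uty (80), Eif2s3y (96) and Ddx3y (116). A lack of sensitivity in the WT library is argued against by other promoters with as many KO tags, of which 218 of 229 (95.2%) were marked in WT. The promoter of Xist, an RNA made in female cells, had 539 tags in WT and 537 in KO. With all 4 genes marked in KO and none in WT, a candidate explanation is that the KO pool held male cells and the WT pool did not. This stays open, because the WT list also held 9 H3K4me3 peaks on Y, of 20 to 824 tags, at positions from 34300692 on. Of these, 2 overlapped KO peaks and 1 lay in a protein-coding gene. The KO list held 6 in all, 4 of them in protein-coding genes. The 9 WT peaks do not by themselves show male cells in the WT pool. Whether reads at the 9 loci came from Y was not tested. The sexes of the mice are not stated in the labels.

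The peak inside Tcf7 lay on chromosome 11 from 52255460 to 52257306, with a score of 64.9 and an FDR of 16.7%. Of all protein-coding genes, 158 (0.742%) overlapped an H3K4me3 peak called in KO alone.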

How the results depend on the processing

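No paired analysis was possible because each group held 1 library. The FDR limit gave no value for overlaps and classes of Tcf1 peaks, since 0 WT and 0 KO Tcf1 peaks passed it. Scaling by total filtered tags and the motif settings were not run. Merged regions were chosen after the data were seen. Main outcomes stayed within their limits in 226 comparisons with an alternative, moved in 39, changed sign in 3 and crossed the bounds of the random lists in 2, and ratios of named genes did the first 3 in 90, 42 and 11. Limits were 95% intervals for shares and single ratios, a factor of 1.5 for counts, and the middle 95% of random lists for list medians. The NK cell receptor median turned to -0.039 at 2.5 kb and -0.040 on merged regions, from within that range. Causes were not tested unless stated.

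With scores of at least 100, 98 WT and 265 KO Tcf1 peaks were left. Overlap of WT with KO Tcf1 peaks was then 54.1%, and overlap with WT H3K4me3 was 22.2% for WT-only, 66.0% for shared and 4.72% for KO-only peaks, with the limit applied to H3K4me3 peaks as well. Promoter shares were 20% for WT-only and 0% for shared peaks. H3K4me3 overlap was 82.7% of WT and 99.5% of KO peaks, with 13 promoters marked in KO alone. Counts near WT-only Tcf1 peaks became 0 for granzymes, 0 for NK cell transcription factors and 0 for T cell markers.

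With an FDR of at most 1%, H3K4me3 overlap was 72.0% of WT and 99.9% of KO peaks, with 7 promoters in KO alone. With equal list lengths, Tcf1 overlap was 11.0%, H3K4me3 overlap 92.9% of WT and 93.2% of KO peaks, and promoters marked in WT alone numbered 480 and in KO alone 137. With the 2.5 kb window, promoter shares were 6.66% for WT-only and 3.40% for KO-only Tcf1 peaks. With the window of 0, erythroid and platelet markers had 0 marked in WT and 0 in KO. At 10 kb, granzymes numbered 0 and T cell markers 1. At 100 kb, NK cell transcription factors numbered 5, and cytotoxic effectors, NK cell receptors, cytokine receptors, B cell and myeloid markers 1 each.

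Per kb of peak the Tcf/Lef and Wnt median came to -0.024 at percentile 54.6 and was no longer outside the random lists, and the median of cytokine receptors turned to 0.13, and genes above 1 numbered 1 and below -1 72. At 2.5 kb the median of cytotoxic effectors, 0.111, passed to percentile 97.6. On merged regions 6 genes lay above 1. Ratios also turned for Klrd1 (0.23), Tcf7 (0.059), Sp110 (-0.19), and H2bc23 and H2ac23 (-0.10 each), by construction through peak width. Hspb9 turned to -0.072 at 2.5 kb, -0.31 at 0 and -0.073 on merged regions, Mrpl54 to -0.14 at 2.5 kb and -0.14 on merged regions, and Tyrobp to 0.071 on merged regions, by construction through the peaks included. Low Tcf1 tag counts, with medians of 23 in WT and 14 in KO, limit what can be said of single peaks.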

Other observations

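Tests of the KO Tcf1 list, of the WT-only H3K4me3 peaks and of promoters that lost a peak near Tcf1 were chosen after the results were seen, as were the values per kb and on merged regions for the hypoxia-response genes. Promoters of genes that respond to low oxygen were a group outside the fixed lists. Egln3, Vegfa and Ak4 had drawn attention to it, so a list of 36 others was written before their ratios were looked at. Of these, 31 were marked in both libraries, and 29 of the 31 had a centred log2 ratio below 0. The lowest were those of the lactate transporter gene Slc16a3 (-1.71, 1479 tags in WT and 543 in KO), Bnip3, which acts in mitophagy (-1.35), Ankrd37 (-1.23) and the glycolytic regulator gene Pfkfb4 (-1.18). P4ha2 was marked in WT alone (333 tags).

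The hypothesis that promoters of hypoxia-response genes may carry less H3K4me3 in KO was met by the measure fixed beforehand. Their median was -0.39, at percentile 0 of 10000 matched random lists, and -0.39 on merged regions. Per kb of peak the median was -0.01 at percentile 27.2, and 16 of 31 genes lay below 0. KO peaks at these promoters were narrower, with a median centred log2 width ratio of -0.40, also at percentile 0. Whether the mark itself or the extent of called peaks differed cannot be told apart here. With 1 library per genotype, any difference between the cultures is confounded with genotype. Pgk1 is also among the housekeeping genes.

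A second hypothesis was that promoters near strong WT-only Tcf1 peaks may lose H3K4me3 in KO. The 40 such genes marked in both had a median of 0.01 at percentile 58.2. Without the Tcf/Lef and Wnt list, the 36 others had a median of 0.03 at percentile 74.5. These medians leave out promoters without a KO peak, so they cannot decide the question. Of 45 genes marked in WT near such a Tcf1 peak, 5 lacked a KO peak, against a mean of 3.92 in random lists matched on WT tags, and 32.4% of the lists had as many. This number lay within the spread of the lists, so the loss of whole peaks stays open. Axin2 was the lowest of the 40.

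The KO Tcf1 list was 5.93 times as long as the WT list. Greater depth of the KO library is argued against by the 115 loci called in both, where the median log2 ratio of KO over WT tags was 0.043 (bootstrap interval 0 to 0.08). Whether signal that remains in KO cells at sites called in WT is binding stays open. In the full lists 13.3% of WT peaks overlapped a KO peak, but 54.1% (interval 44.3 to 63.6%) with scores of at least 100. The KO mice lack Tcf7, and overlap alone cannot tell binding from background signal of the antibody. Such binding would bear on the 115 of 5139 KO peaks at these sites. Binding in KO cells at Tcf1 sites not called in WT stays open too. KO-only peaks lay near 3 members of the Tcf/Lef and Wnt list, and 87.2% of random lists had as many. A lower background assumed by the peak caller for the KO library may account for it. At the same loci the fold enrichment per tag was higher in KO by a median of 0.41 on the log2 scale (interval 0.33 to 0.47), in 95 of 115 cases.

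H3K4me3 peaks called in WT alone numbered 3102, against 396 in KO alone. Of the former, 99.0% had fewer tags than the WT median of 365, so lower sensitivity of the KO library for weak peaks may account for most of them. Loci of piled-up reads seen with the Tcf1 antibody in both genotypes were another candidate source, and 1.58% (49 peaks) overlapped such a locus. There were only 115 such loci for the 3102 peaks, so a large share was not possible beforehand. The test thus cannot decide on piled-up reads outside these loci. Of the 30 strong ones below, 9 (30%) did. These 9 lay away from promoters, where this source stays open, and 0 of the 9 at promoters overlapped such a locus. Of WT peaks with at least the median tags, 30 of 6889 (0.435%, interval 0.305 to 0.621%) lacked a KO partner, against 0 of 5541 in the reverse direction. The 9 of these 30 at promoters were set beside WT peaks of like strength. Of the 418 WT peaks nearest to them in tags, score and fold enrichment, 395 (94.5%, interval 91.9 to 96.3%) had a KO partner. Fcgr3 was the exception among the 9, with 62% of its 50 neighbours found. For the 21 others the share was 80.2%, and 6 of them had over 90% of their neighbours found. The 30 were picked for lacking a KO partner, which nearly all WT peaks of at least the median tags have. High shares were thus likely beforehand, so sensitivity and genotype cannot be told apart for the 9 or for the 21. A biological effect of genotype on the weak peaks was not tested.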
